A study of Mus musculus with 24 samples.

How the data were processed

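The data are 24 mRNA sequencing libraries of cultured mouse granulosa cells, 4 in each of 6 groups defined by siRNA, hCG and time, as the sample titles give them. Libraries were made with a stranded mRNA kit and read over 151 cycles from both ends on 2 lanes, per the labels' protocols. The authors deposited a table of estimated counts per Entrez gene for each library, which are not scaled to a common total. They also deposited tables of their own comparisons with log2 fold changes, mean log2 CPM and p-values with adjusted p-values. One of the deposited tables also holds log2 CPM per library that differ from log2 CPM of the estimated counts by an amount that is nearly constant within a culture date; these values entered no test. The submitters' processing notes name Salmon 1.4.0, R 4.1.0, edgeR, limma and the genome build GRCm39, without the role or order of each tool, and the authors' model, block and method of p-value adjustment are not given in the sources used here. Salmon assigns reads that match several transcripts by estimate, so near-identical gene copies can trade counts between libraries.

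The deposited estimated counts were rounded to whole numbers before testing. Library totals ranged from 26.2 M to 45.4 M with a median of 39.2 M. Genes were kept with edgeR's filterByExpr over the 6 groups, which left 15405 of 39253 genes holding 99.97% of the counts; 14362 genes carry a mark of being kept in the authors' deposited table. All 24 libraries entered 1 quasi-likelihood fit (glmQLFit and glmQLFTest in edgeR 4.0.16, R 4.3.3) with TMM scaling and no block, and 7 contrasts were tested with Benjamini-Hochberg adjustment and a threshold of 0.05. The contrasts were hCG at 4 h and at 12 h, Nts siRNA at 4 h and at 12 h, the differences of these effects between the times, and time in control cells. Standard errors are the log2 fold change divided by the root of the F statistic. CPM values use TMM-scaled library sizes, and log2 CPM used a prior count of 2. In each of 36 pairs of libraries from the same group, counts differed by more than sampling noise (chi-square per degree of freedom from 24.2 to 472), so none looked like a repeat deposit of another library. This does not show that they are biological replicates; each library counted as 1 replicate because the titles give it its own label. The labels say that each culture pooled cells from 2 mice but not whether A_2 and B_2, which share a date, were separate pools; p-values then measure only the spread between these samples, which may be partly technical.

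The replicate labels recur in every group and the titles give each label a culture date, so a label marks a shared date, and it was used as a block in an alternative fit. As a check, deviations from the group means were correlated between same-label libraries of the groups compared, over 10798 genes with a mean log2 CPM of at least 2. Of 20 such pairs 17 had a correlation over 0.1, with a median of 0.529, a lowest of −0.692 and a highest of 0.957. The main fit leaves this pairing out, so differences between labels count as spread in its p-values. For Nts siRNA at 12 h, for example, 25 genes passed without the label block and 91 with it. The first 3 principal components held 48.3%, 24.6% and 15.4% of the variance.

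There were 28 gene lists for ovulation, steroid and cholesterol synthesis, signalling, stress, matrix and metabolism and for markers of other cell types. Of these, 27 had at least 5 tested genes; of the 15 mitochondrially encoded transcripts, 0 were in the table, so that list gave no value. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) and adjusted over the lists within each contrast, and again with a correlation estimated for each list and with the label block. Camera compares a list with other genes; fry, run as well, tests whether a list's genes move one way on balance. Where a list count is given as adjusted over the list alone, only its members entered the adjustment. In hCG and siRNA contrasts, the genes named were Nts, then up to 8 with the largest changes each way that passed, moved the same way under all 4 labels, averaged at least 5 CPM in the higher group and had a gene symbol other than a predicted-gene name. For the other contrasts up to 5 each way were named without the per-label condition, and for each described list up to 4 members with the smallest adjusted p, plus members that did not pass. Exceptions are stated as chosen after their values were seen; some list members were also named when more than 4 had passed.

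The groups, tests, lists, naming rule and alternatives described so far were set before the data were examined. The alternatives were the label block, a block of culture date, RLE size factors, no filter on low counts, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom, only the libraries of the contrast, a minimum change of 1.5-fold, and leaving out each replicate label. Others were added after seeing the data: leaving out the control library A_1 at 12 h, with and without the label block, and testing only genes without siRNA seed sites. For the relation between the hCG and siRNA effects, 100 simulated data sets per setting gave the values without effects, and the siNC libraries with hCG were split into parts of 2; the simulations with a spread from the blocked fit and with the hCG effect kept were added after the first values had been seen.

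The test was checked on simulated counts drawn from the means and library sizes of the real libraries, with 200 genes changed. Changed genes were picked only from those with a mean above 2 CPM in the groups compared, so the recovery does not cover genes below that. The simulated spread was that of the fit without a block, and the simulated libraries held no pairing by label. For hCG at 4 h, 19.4%, 70.1% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered among 15234 genes, and 6.02% of the calls were false. For Nts siRNA at 12 h, the shares were 20.9%, 62.7% and 95.5% among 15242 genes, with 3.25% false calls.

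Gene positions, transcript sequences and 3′ UTRs came from GENCODE vM21 on GRCm38, which is not the build named in the processing notes, and no coordinate was converted. Each 7-base sequence found in the 3′ UTR of at least 20 genes was tested for a shift of the siRNA effect, adjusted for UTR length, GC content and mean level, over 10446 genes. Scans and figures used Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9. The siRNA sequences are not given in the sources used here.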

Results

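Granulosa cells, the follicle cells that surround the oocyte and make ovarian steroids, were isolated from 23-day-old C57BL/6 mice 48 h after pregnant mare serum gonadotropin (PMSG), a hormone that drives follicle growth. Cells pooled from 2 mice were transfected for 3 h with a control siRNA (siNC) or an siRNA against Nts (siNTS). They were then cultured for 4 h or 12 h with or without human chorionic gonadotropin (hCG), a hormone that acts on the luteinizing hormone receptor and sets off ovulation. Stranded mRNA sequencing gave 24 libraries in 6 groups of 4: siNC without hCG (control), siNC with hCG and siNTS with hCG, each at 4 h and at 12 h. The libraries of each group carried the labels A_1, A_2, B_2 and B_3. They came from 3 culture dates, with A_2 and B_2 on a shared date. Estimated counts per library summed to between 26.2 M and 45.4 M, with a median of 39.2 M. Of 39253 listed genes, 15405 had enough counts to test. Abundances are given in CPM, counts scaled to library totals after TMM normalization, as mean ± SD (n = 4 libraries). Effects are log2 fold changes ± standard error, and adjusted p-values come from edgeR's quasi-likelihood test unless another method is named. A culture with siNTS and no hCG was not analysed here, so the siRNA effect was measured in the presence of hCG.

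Nts encodes neurotensin, a secreted peptide, and was the target of the siRNA. Nts (Entrez 67405) stood at 16.1, 28.7, 22.9 and 180 CPM in the siNC libraries A_1, A_2, B_2 and B_3 after 4 h of hCG, and at 1.99, 4.39, 4.16 and 42.9 CPM in the matching siNTS libraries. After 12 h of hCG, Nts measured 2.69, 1.56, 1.49 and 9.67 CPM with siNC and 0.154, 0.121, 0.0764 and 2.73 CPM with siNTS. Without hCG, Nts measured 7.57, 2.47, 2.87 and 9.82 CPM at 4 h and 0.0254, 0.175, 0.185 and 0.871 CPM at 12 h. Nts was thus lower with siNTS under every replicate label at both times, in the direction that the labels state. The B_3 library was the highest of its group in all 6 groups.

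With hCG for 4 h, Nts rose from 5.68 ± 3.60 to 61.9 ± 78.9 CPM, a log2 fold change of 3.44 ± 1.08 (adjusted p = 0.029), and 2.81 (adjusted p = 8.7e-05) with the replicate label as a block. Without the block that call was lost without label A_2 (adjusted p = 0.13) or without B_2 (adjusted p = 0.10). At 12 h, Nts averaged 3.85 ± 3.92 CPM with hCG and 0.314 ± 0.378 CPM without (log2 fold change 3.60 ± 1.29, adjusted p = 0.059). It passed when the replicate label entered as a block (3.78, adjusted p = 0.00017). The siRNA changed Nts by a log2 of −2.22 ± 1.02 at 4 h (adjusted p = 1), which did not pass. The value was −2.46 (adjusted p = 0.053) with the label as a block, and with culture date as the block −2.47 (adjusted p = 0.043). At 12 h the Nts change was −2.34 ± 1.16 (adjusted p = 1), and −2.76 (adjusted p = 0.022) with the label block. It was −4.01 (adjusted p = 0.16) without label B_3 and −3.39 (adjusted p = 1) with limma-voom. On mouse build GRCm38, the Nts gene lies on the minus strand of chromosome 10, from 102481756 to 102490486, with 4 exons and a 3′ UTR of 578 bases in a transcript of 1248 bases.

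**Figure D1:**
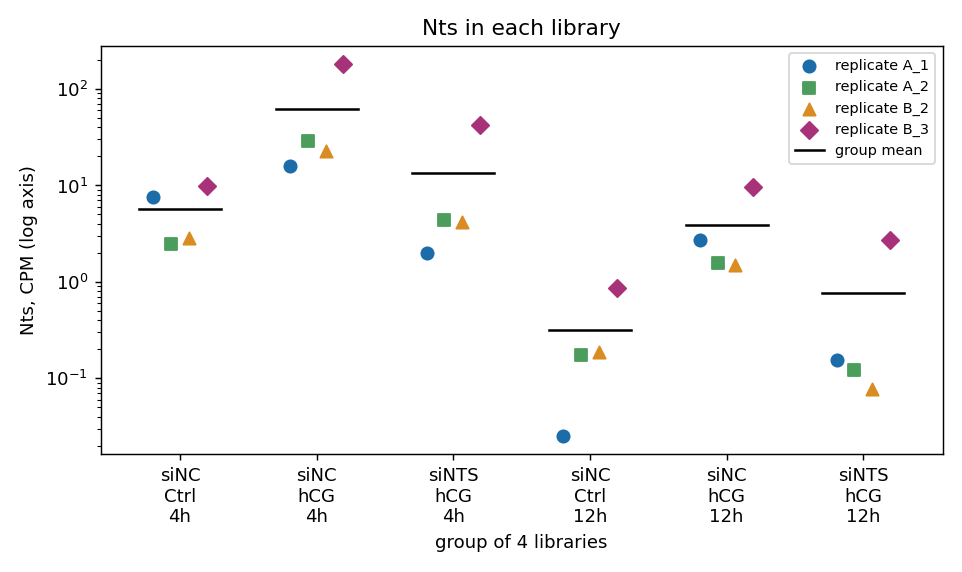
Nts abundance in each of the 24 libraries (CPM, log axis) for the 6 groups; marker shapes are replicate labels and bars are group means (n = 4). With hCG, each siNTS library lies below the siNC library of the same label, for example 1.99 against 16.1 CPM for A_1 at 4 h, and B_3 is highest in every group.

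The comparison of siNC cells with and without hCG for 4 h asked which genes the ovulatory signal changes early. Adcyap1 (Entrez 11516), the gene for the neuropeptide PACAP, rose from 1.405 ± 0.370 to 129 ± 32.6 CPM, a log2 fold change of 6.51 ± 0.40 (adjusted p = 8.6e-10). Star (Entrez 20845), which carries cholesterol into mitochondria for steroid synthesis, rose from 25.1 ± 22.1 to 738 ± 174 CPM (4.88 ± 0.46, adjusted p = 2.1e-07). The EGF-like growth factor gene Ereg (Entrez 13874) rose from 4.98 ± 4.66 to 203 ± 114 CPM (5.34 ± 0.59). The peptide genes Nmu (5.66 ± 0.55) and Pthlh (5.61 ± 0.37), the receptor-modifying protein gene Ramp3 (5.44 ± 0.48), the granzyme gene Gzmb (6.26 ± 0.49) and Ly6m (6.37 ± 0.72) rose by similar factors. Among the genes that fell most, Mro (Entrez 71263) went from 118 ± 20.3 to 16.5 ± 0.456 CPM (−2.84 ± 0.18, adjusted p = 1e-09). The scavenging chemokine receptor gene Ackr3 (−2.78 ± 0.33), Tdrd5 (−2.55 ± 0.26), Smtnl2 (−2.39 ± 0.41), Atoh8 (−2.31 ± 0.32), Slc24a4 (−2.28 ± 0.30) and the hydroxysteroid dehydrogenase gene Akr1c14 (−2.19 ± 0.27) also fell. In all, 1224 genes rose and 1712 fell at an adjusted p under 0.05, of which 587 rose and 569 fell at least 2-fold. With the replicate label as a block 4642 genes passed. In a fit of only the control and hCG groups at 4 h 1770 passed, and 1283 passed without label A_2 and 1693 without B_2.

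Of 30 ovulatory genes tested, 26 rose and 0 fell with hCG at 4 h (27 and 1 adjusted over the list alone). The list stood above other genes (camera adjusted p = 1.3e-30; adjusted p = 0.025 with an estimated correlation). They included the chemokine receptor gene Cxcr4 (4.38 ± 0.29, from 3.64 ± 1.46 to 76.2 ± 21.1 CPM), the Wnt-binding gene Sfrp4 (4.04 ± 0.32), Tnfaip6, which helps build the cumulus matrix (3.48 ± 0.34), and Snap25 (4.67 ± 0.50). The prostaglandin synthase gene Ptgs2 rose by 3.03 ± 0.71 (adjusted p = 0.0040), the progesterone receptor gene Pgr by 3.42 ± 0.56 (adjusted p = 0.00016) and Areg by 4.00 ± 0.60 (adjusted p = 6.4e-05). These 3 members were chosen after their values were seen. Of 23 genes of preovulatory granulosa cells, 0 rose and 11 fell (2 and 12 adjusted over the list alone). Their camera adjusted p was 7.6e-05 (adjusted p = 0.066 with an estimated correlation). Those that fell included Igf1 (−1.96 ± 0.21), the gap junction gene Gja1 (−1.34 ± 0.20, from 4431 ± 786 to 1752 ± 205 CPM), the hedgehog ligand gene Ihh (−1.88 ± 0.28) and the anti-Müllerian hormone receptor gene Amhr2 (−1.06 ± 0.15). The luteinizing hormone receptor gene Lhcgr (0.43 ± 0.41, adjusted p = 0.52) and the aromatase gene Cyp19a1 (0.17 ± 0.50, adjusted p = 0.85; −0.01 without label B_3) did not pass at 4 h. Of 18 steroid synthesis genes 6 rose and 2 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.0050, and adjusted p = 0.072 with an estimated correlation). The lipoprotein receptor gene Scarb1 rose by 2.59 ± 0.21 and the side-chain cleavage gene Cyp11a1 by 1.47 ± 0.26. Of 23 cholesterol synthesis genes 7 rose and 0 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.019, and adjusted p = 0.84 with an estimated correlation). Cyp51 (0.74 ± 0.12) was among them.

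Signalling genes also moved with hCG at 4 h. Of 26 immediate early and cAMP-responsive genes 14 rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 2.3e-13, and adjusted p = 0.17 with an estimated correlation). The phosphodiesterase genes Pde4b (log2 fold change 3.45) and Pde4d (2.39) rose among them. Of 19 ERK pathway targets and feedback genes 7 rose and 0 fell (9 and 1 adjusted over the list alone; camera adjusted p = 4.3e-05, and adjusted p = 0.41 with an estimated correlation). They included the phosphatase genes Dusp4 (1.54) and Dusp5 (1.62) and the inhibitor gene Spry2 (1.39). Of 20 proteases and inhibitors 9 rose and 2 fell (the same counts adjusted over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.46 with an estimated correlation). The urokinase gene Plau rose by 2.20, and Mmp11 stood at −1.32. Of 21 heat shock and oxidative stress genes 5 rose and 1 fell (the same counts adjusted over the list alone; camera adjusted p = 0.022, and adjusted p = 0.43 with an estimated correlation). Srxn1 rose by 1.39 and Txnrd1 by 1.10. Of the 10 genes listed for neurotensin, its receptors and peptide processing, 7 were tested, and 5 rose and 0 fell (5 and 0 adjusted over the list alone). The list's camera adjusted p was 0.00091, and 0.21 with an estimated correlation. Besides Nts, itself a member, the proprotein convertase genes Pcsk5 (2.22), Furin (0.69) and Pcsk6 rose, as did Sorl1. The call on Sorl1 was lost without label A_2 (adjusted p = 0.071) and that on Pcsk6 without B_2 (adjusted p = 0.0505). The receptor genes Ntsr1 and Ntsr2 were not among those that rose. Of 30 interferon-stimulated genes 1 rose and 7 fell (1 and 9 adjusted over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.77 with an estimated correlation). Xaf1 stood at −1.44 and Bst2 at −0.86. The call on Xaf1 was lost without label A_1 (adjusted p = 0.069) and that on Bst2 without A_2 (adjusted p = 0.078).

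The other lists did not pass as lists at 4 h. Members that rose and fell numbered 2 and 2 of 30 for the cell cycle, 2 and 0 of 23 for collagen and matrix, 3 and 3 of 23 for hypoxia and angiogenesis and 2 and 2 of 19 for glycolysis. They numbered 2 and 1 of 19 for cytokines and NF-kB targets, 1 and 1 of 21 for the unfolded protein response, 0 and 3 of 22 for p53 targets, 5 and 3 of 19 for the circadian clock and 1 and 2 of 13 for the RNA interference machinery. Marker lists of other cell types gave 1 and 0 of 8 for theca and interstitial cells, 0 and 0 of 9 for fibroblasts, 0 and 0 of 14 for oocytes and 1 and 0 of 13 for immune cells. The markers gave 3 and 0 of 9 for endothelium, 1 and 1 of 8 for smooth muscle, 0 and 0 of 7 for surface epithelium and 0 and 0 of 6 for erythrocytes. The smallest camera adjusted p among these was that of the endothelial list (0.058; 0.027 with the label block; without it, adjusted p = 0.17 with an estimated correlation). In it the VEGF receptor gene Kdr rose by 4.06 ± 0.42, from 3.01 ± 1.16 to 50.6 ± 17.5 CPM. Adjusted over the list alone, counts differed for the cell cycle (1 and 1), collagen (1 and 0), p53 targets (0 and 1) and the clock (5 and 5). Medians, means and tests differed in sign for the cell cycle (median −0.04, test upward), smooth muscle (median −0.22, mean 0.05) and surface epithelium (median −0.13, test upward).

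At 12 h, the comparison with and without hCG asked which genes the signal changes late. Cyp11a1, whose product starts steroid synthesis from cholesterol, rose from 285 ± 39.5 to 2713 ± 482 CPM (3.25 ± 0.27). Fdx1, its electron donor, rose from 273 ± 61.7 to 1493 ± 169 CPM (2.45). Cxcr4 rose from 0.710 ± 0.254 to 50.5 ± 9.01 CPM (6.14 ± 0.32, adjusted p = 4.8e-11), and Adcyap1 from 0.0391 ± 0.0503 to 8.30 ± 2.55 CPM (7.59 ± 0.55). The asialoglycoprotein receptor gene Asgr1 (Entrez 11889; 5.45 ± 0.39), the peptide genes Apela (Entrez 100038489; 5.59 ± 0.53) and Edn2 (Entrez 13615; 4.66 ± 0.64), Ramp3 (5.87 ± 0.62), Ereg (5.50 ± 0.63) and Slc16a11 (4.70 ± 0.41) rose as well. Slc24a4 (Entrez 238384) fell from 12.8 ± 2.60 to 0.775 ± 0.196 CPM (−4.04 ± 0.34), and the vascular growth factor gene Angpt2 from 149 ± 46.3 to 20.5 ± 4.31 CPM (−2.86 ± 0.30). Ackr3 (−3.45 ± 0.35), the natriuretic peptide receptor gene Npr3 (−2.96 ± 0.45), Ctnna2 (−2.87 ± 0.42), the Wnt inhibitor gene Frzb (−2.84 ± 0.36) and Ihh (−2.76 ± 0.29) fell too. Vcam1 also fell (−3.66 ± 1.06, adjusted p = 0.019), but its control mean of 22.0 ± 36.7 CPM rested on B_3 at 77.1 CPM against 3.96 CPM in the next library. The call was lost without label A_2 (adjusted p = 0.083) or B_2 (adjusted p = 0.067). It was also lost with limma-voom (−2.47, adjusted p = 0.081) and with only these groups (adjusted p = 0.065). In A_1, A_2 and B_2, Vcam1 stood at 3.43, 3.96 and 3.54 CPM in control cells and at 1.03, 0.884 and 1.07 CPM with hCG. In all, 1260 genes rose and 1288 fell, of which 600 rose and 564 fell at least 2-fold. Under the label block 4164 passed, and 1268 passed without label A_2 and 1583 without B_2.

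By list, 20 of 23 cholesterol synthesis genes rose at 12 h and 0 fell (20 and 0 adjusted over the list alone; camera adjusted p = 2.9e-15, and adjusted p = 0.057 with an estimated correlation). The reductase gene Dhcr7 rose from 107 ± 13.9 to 350 ± 25.7 CPM (1.71 ± 0.17), and Cyp51 by 1.10. Of 18 steroid synthesis genes 11 rose and 2 fell (the same counts adjusted over the list alone; camera adjusted p = 1.1e-07, and adjusted p = 9.7e-04 with an estimated correlation). Star rose by 4.15 ± 0.45 and Scarb1 by 2.17. Of 30 ovulatory genes 20 rose and 1 fell (23 and 1 adjusted over the list alone; camera adjusted p = 2.2e-25, and adjusted p = 0.019 with an estimated correlation). Sfrp4 rose by 3.49 and the transcription factor gene Runx2 by 2.48. Areg rose by 4.45 ± 0.68 (adjusted p = 5.9e-05) and Ptgs2 by 2.99 ± 0.72 (adjusted p = 0.0053), a call lost without A_2 (adjusted p = 0.094) or B_2 (adjusted p = 0.050). Pgr stood at 1.14 ± 0.69 (adjusted p = 0.29), and at 1.16 (adjusted p = 0.011) with the label block. Of 23 preovulatory genes 1 rose and 9 fell (2 and 12 adjusted over the list alone; camera adjusted p = 4.9e-06, and adjusted p = 0.019 with an estimated correlation). Igf1 (−2.45), the estrogen receptor gene Esr2 (−2.15) and follistatin (Fst, −1.63) fell. Lhcgr rose from 52.9 ± 14.4 to 329 ± 91.4 CPM (2.64 ± 0.43, adjusted p = 0.00012), and Cyp19a1 did not pass (0.84 ± 0.52, adjusted p = 0.31), though it did without label B_3 (1.03, adjusted p = 0.013) and with only these groups (0.84, adjusted p = 0.037).

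Of 26 immediate early genes 12 rose and 1 fell at 12 h (13 and 1 adjusted over the list alone; camera adjusted p = 0.00049, and adjusted p = 0.82 with an estimated correlation). Pde4d rose by 3.36 and Nr4a3 by 2.37. Of 19 glycolysis genes 5 rose and 0 fell (the same counts adjusted over the list alone; camera adjusted p = 0.0063, and adjusted p = 0.68 with an estimated correlation). The hexokinase gene Hk2 rose by 1.81 and the pyruvate kinase gene Pkm by 0.62. Of 20 proteases and inhibitors 7 rose and 2 fell (the same counts adjusted over the list alone; camera adjusted p = 0.023, and adjusted p = 0.82 with an estimated correlation). The inhibitor gene Timp1 rose by 2.11 and the plasminogen activator gene Plat by 1.30. The other lists did not pass at 12 h. Among them, 7 of 19 clock genes rose and 6 fell, with Rora at 1.99 and Nr1d2 at −0.89, and that list's median (−0.12) and mean (0.22) differed in sign. Within the hypoxia and angiogenesis list, of which 5 of 23 rose and 2 fell, the peptide gene Apln rose from 8.51 ± 0.91 to 120 ± 36.9 CPM (3.82 ± 0.25). The matrix protein gene Thbs1 fell from 1893 ± 147 to 372 ± 111 CPM (−2.35). The list of theca and interstitial markers had 1 of 8 higher, Lhcgr, and 3 lower (median −0.31, mean 0.22). Among immune markers 1 rose, among endothelial markers 2 rose, among smooth muscle markers 3 fell and among fibroblast markers 1 fell. Oocyte, surface epithelium and erythrocyte lists had 0 members that passed.

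**Figure D2:**
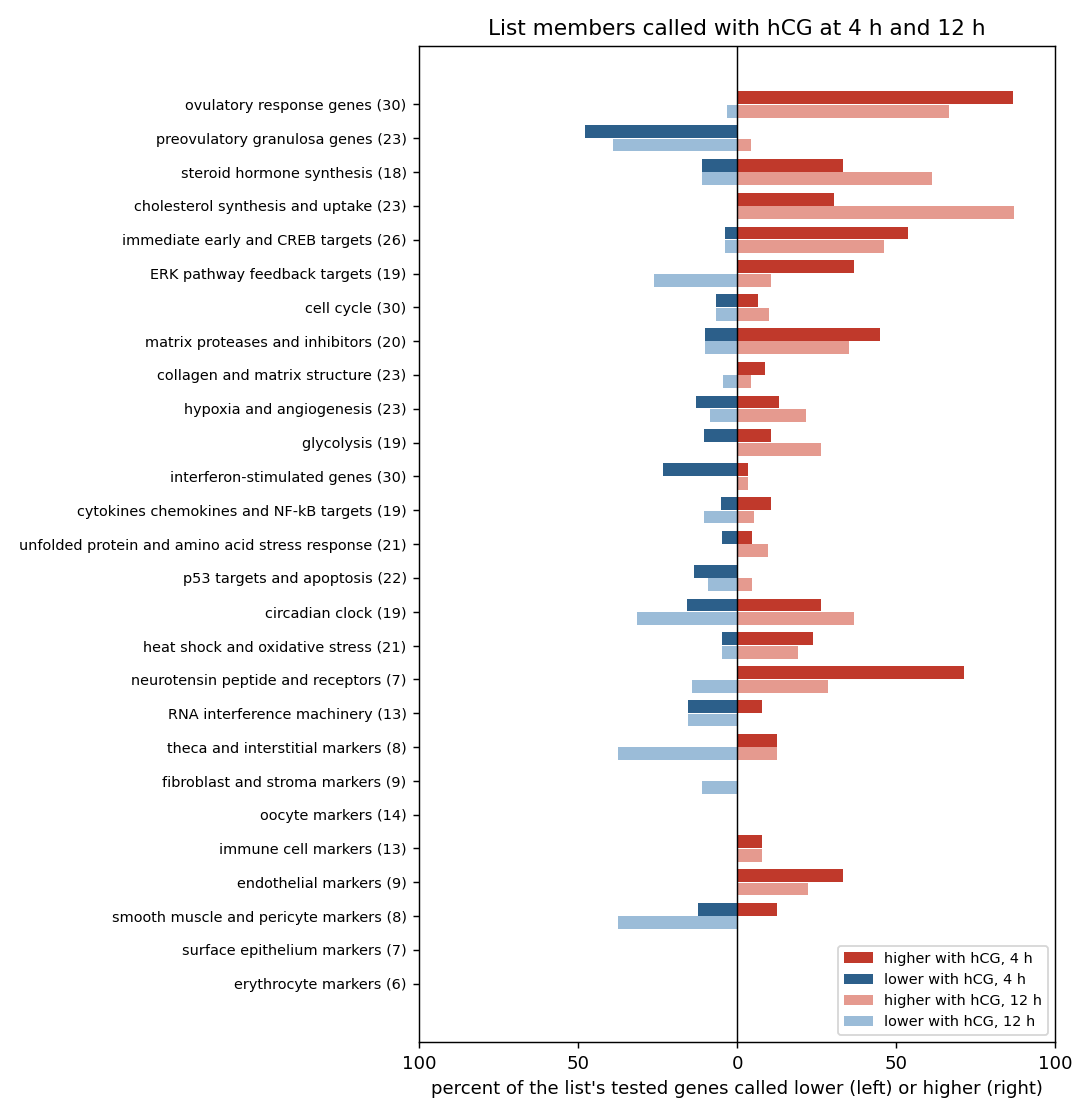
Share of the tested genes of each list (percent) that rose or fell with hCG in siNC cells at 4 h and at 12 h (adjusted p under 0.05). Cholesterol synthesis went from 7 of 23 genes at 4 h to 20 of 23 at 12 h, and the ovulatory list from 26 to 20 of 30.

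**Figure D3:**
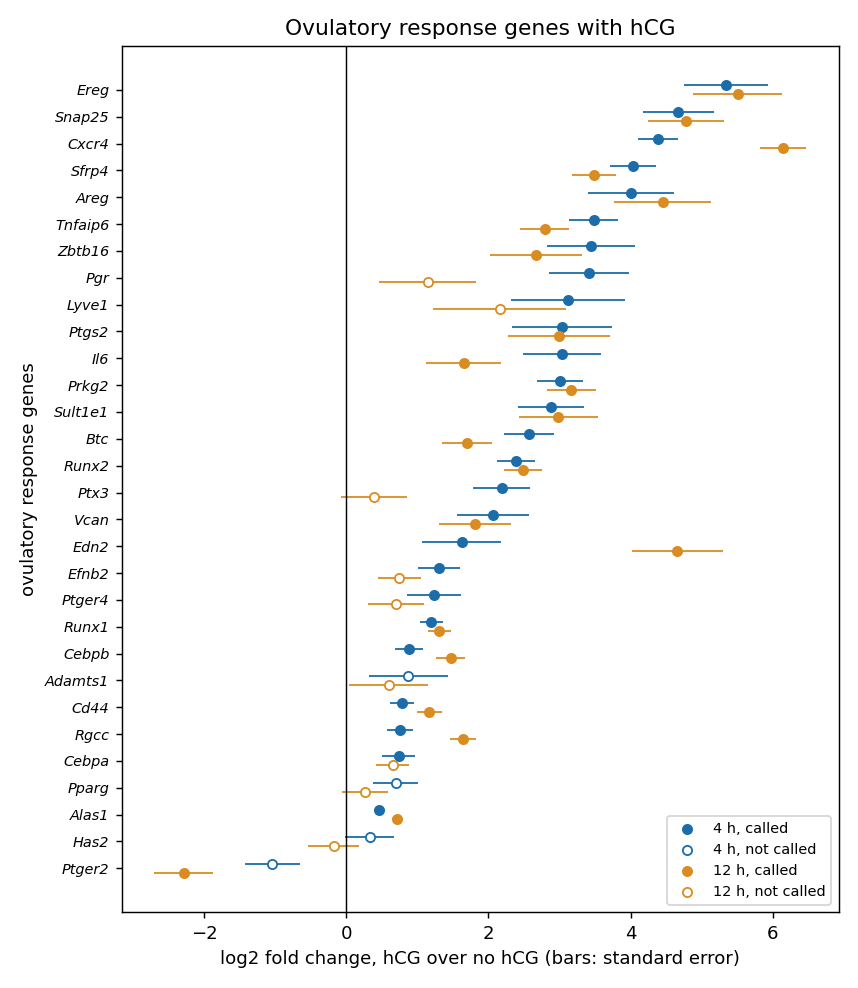
Log2 fold change ± standard error with hCG for each tested ovulatory gene at 4 h and 12 h (n = 4 libraries per group); filled points passed the test. Areg stood at 4.00 and 4.45, and Pgr at 3.42 and 1.14.

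The hCG effects at 4 h and 12 h were compared directly, as the difference between the log2 fold changes. Apln (difference 3.44 ± 0.34, adjusted p = 3.4e-06), the prostaglandin F receptor gene Ptgfr (3.37 ± 0.39), the receptor-modifying gene Ramp1 (3.66 ± 0.65), the cadherin gene Cdh15 (3.33 ± 0.51) and the haptoglobin gene Hp (3.71 ± 0.58, adjusted p = 0.00081) had the most positive differences. Pnoc, a neuropeptide precursor gene (−3.58 ± 0.35), Nmu (−3.23 ± 0.87, adjusted p = 0.039), Arl4d (−3.15 ± 0.47), Adgrv1 (−3.10 ± 0.22, adjusted p = 2.3e-08) and Npr3 (−2.99 ± 0.60) had the most negative. Without label A_2, the calls on Hp (adjusted p = 0.052), Nmu (adjusted p = 0.16) and Npr3 (adjusted p = 0.066) were lost. Nmu was also lost without B_2 (adjusted p = 0.23) or B_3 (adjusted p = 0.15). In all 586 genes passed, 362 with a more positive and 224 with a more negative effect at 12 h. Under the label block 2174 genes passed, with culture date as a block 1748, with DESeq2 1061 and with no filter on low counts 385. Without label A_1 314 passed, without A_2 69 and without B_2 161. Of the genes with a more positive effect, 151 had risen only at 12 h, 140 had fallen only at 4 h and 25 fell at 4 h and rose at 12 h.

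The 7 of 19 ERK pathway genes that passed had lower hCG effects at 12 h than at 4 h (0 and 8 adjusted over the list alone; camera adjusted p = 9.7e-09, and adjusted p = 0.42 with an estimated correlation). Spry2 stood at −2.20 ± 0.32 (adjusted p = 0.00032). Of 23 cholesterol synthesis genes 4 had higher effects at 12 h and 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 1.6e-07, and adjusted p = 0.43 with an estimated correlation). Dhcr7 stood at 1.43 ± 0.24 (adjusted p = 0.0015; 0.060 without label A_2). Of 30 interferon-stimulated genes 3 had higher effects at 12 h (10 adjusted over the list alone; camera adjusted p = 2.9e-06, and adjusted p = 0.77 with an estimated correlation). Of 18 steroid synthesis genes 2 did (2 adjusted over the list alone; camera adjusted p = 0.034, and adjusted p = 0.42 with an estimated correlation). Cyp11a1 stood at 1.78 ± 0.36 (adjusted p = 0.0069; 0.056 without B_2 and 0.072 without B_3). The immediate early list (camera adjusted p = 0.00074, and adjusted p = 0.95 with an estimated correlation), the neurotensin list (0.0027 and 0.43), the RNA interference list (0.026 and 0.77) and the NF-kB list (0.033 and 0.95) had lower effects at 12 h. In these 4 lists 1, 1, 0 and 0 members passed (3, 2, 0 and 0 adjusted over the list alone), with the convertase gene Pcsk2 at −2.17. The clock gene Rora had a higher effect at 12 h (1.90, adjusted p = 0.00028). Between the times, 546 genes rose at both (100 for independent lists of these sizes) and 551 fell at both (143). Another 11 rose at 4 h and fell at 12 h (102), and 25 fell at 4 h and rose at 12 h (140).

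The siNTS and siNC cells given hCG for 4 h were compared to find genes that change with the Nts siRNA. The calpain gene Capn10 (Entrez 23830) fell from 33.3 ± 1.94 to 15.2 ± 1.13 CPM, a log2 fold change of −1.13 ± 0.17 (adjusted p = 0.022), and was the only gene of 15405 to pass. The call was lost without A_2 (adjusted p = 0.85), B_2 (adjusted p = 1) or B_3 (adjusted p = 0.79). The endosomal sorting gene Vps37a (−0.91, adjusted p = 0.50) and the chaperone gene Dnajc16 (−0.70, adjusted p = 0.50) did not pass and were chosen after their values were seen. They passed with Capn10 when the label entered as a block (−0.93, adjusted p = 0.00054, and −0.72, adjusted p = 0.019), for 3 genes in all. All 3 carry TGACAAA, a possible seed site of the siRNA, in the 3′ UTR. Dependence on Nts and seed pairing therefore cannot be told apart for them without a second siRNA. Among genes without seed sites 0 passed at 4 h. At an unadjusted p under 0.05 there were 131 genes, and DESeq2 called 6. The ovulatory genes Ptgs2 (−0.33), Pgr (−0.01), Areg (0.06) and Ereg (0.03) did not pass. As lists, the interferon-stimulated genes (camera adjusted p = 6.4e-07) and clock genes (0.0092) stood lower and the heat shock genes (0.0056) higher, with 0 members passing over all genes or adjusted over the list alone. Each had an adjusted p = 0.96 with an estimated correlation; by fry, which asks whether a list moved one way on balance, the adjusted p was 0.99. With the label block the neurotensin list (0.0056), which contains Nts itself, and the NF-kB list (0.036) also stood lower (without the block, adjusted p = 0.96 and 0.98 with an estimated correlation).

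At 12 h, 18 genes fell and 7 rose in siNTS cells with hCG. Capn10 fell from 34.6 ± 3.59 to 13.5 ± 1.87 CPM (−1.35 ± 0.17, adjusted p = 0.0014), and Vps37a (Entrez 52348) from 89.7 ± 11.8 to 39.7 ± 10.3 CPM (−1.18 ± 0.20, adjusted p = 0.016). The sphingomyelin synthase gene Sgms2 (Entrez 74442) fell from 142 ± 17.4 to 72.8 ± 4.11 CPM (−0.96 ± 0.18). The noncoding RNA Norad (Entrez 347740), which binds Pumilio proteins, fell from 317 ± 21.03 to 176 ± 24.7 CPM (−0.85 ± 0.14, adjusted p = 0.016). The zinc finger genes Zfp984 (Entrez 100041677; −1.24 ± 0.22), Zfp946 (−0.91) and Zfp512 (−0.79 ± 0.13) and the chaperone gene Dnajc16 (Entrez 214063; −0.78 ± 0.15) fell too. The Wnt receptor gene Ryk (Entrez 20187) rose from 54.5 ± 2.73 to 92.2 ± 9.71 CPM (0.76 ± 0.11, adjusted p = 0.0049). The heme synthesis gene Cpox (Entrez 12892) rose from 73.1 ± 1.75 to 118 ± 12.7 CPM (0.69 ± 0.12), and Rbm18 (Entrez 67889) from 23.2 ± 1.45 to 41.2 ± 2.48 CPM (0.83 ± 0.14). The glucosylceramide synthase gene Ugcg (Entrez 22234; 0.65 ± 0.12) and the microtubule gene Slain2 (Entrez 75991; 0.49 ± 0.10) rose as well. Of the 17 genes that fell and have an annotated 3′ UTR, 17 carried a 6-base core and 14 the 7-base site TGACAAA in it, against 32.3% and 13.5% of 13544 genes. Site and core were chosen by the siRNA effect at 12 h in these same libraries, so these shares are no independent test. The comparison was not matched for UTR length. TGACAAA occurs once in the coding sequence of Nts. Under the label block 91 genes passed, with culture date 75, with DESeq2 61, with a filter at 1 CPM 38, with no filter 14 and with only these groups 1. Without A_1 40 passed, and without A_2, B_2 or B_3 edgeR called 0, against 560 genes at an unadjusted p under 0.05 with all libraries.

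Ptgs2 (−0.18), Pgr (0.32), Areg (0.32) and Ereg (0.19) did not pass at 12 h, and 0 members of the 27 lists tested passed over all genes. Adjusted over the list alone, 1 gene of the RNA interference machinery fell. Camera placed 10 lists apart from other genes, none of which held with an estimated correlation (adjusted p of 0.64 or more). By fry, which asks whether a list moved one way on balance and not whether it differed from other genes, 0 lists passed (adjusted p of 0.90 or more). These were the interferon-stimulated genes (2.0e-06), RNA interference machinery (0.031) and endothelial markers (0.045), which stood lower. Those that stood higher were glycolysis (4.4e-05), ERK targets (0.00033), hypoxia (0.0026), oocyte markers (0.012), smooth muscle markers (0.025), immediate early genes (0.029) and the unfolded protein response (0.031). The summed CPM of the 14 oocyte markers was 21.6 in the siNTS library A_1 with hCG at 12 h, against 4.14 to 7.52 in the other siNTS libraries and 4.55 to 5.31 in the siNC libraries. With the label block the oocyte list (0.059) and the endothelial list (0.077) no longer passed, and the neurotensin list, which contains Nts, did (lower, 0.014; without the block, adjusted p = 0.80 with an estimated correlation).

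**Figure D4:**
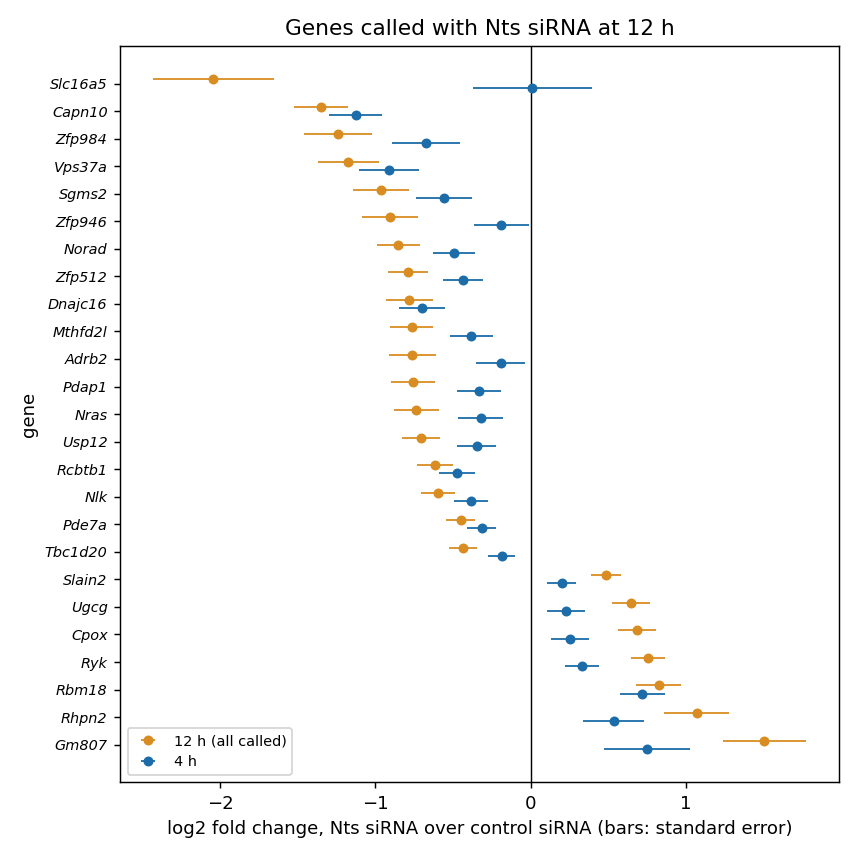
Log2 fold change ± standard error (siNTS against siNC, both with hCG, n = 4 libraries per group) at 12 h and 4 h for the 25 genes that passed at 12 h. The 18 that fell and the 7 that rose are ordered by their 12 h value, with Capn10 at −1.35 at 12 h and −1.13 at 4 h.

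The difference between the siRNA effects at 12 h and 4 h passed for 0 genes with edgeR, with 116 at an unadjusted p under 0.05. DESeq2 called 1 gene, Snurf, and limma-voom 0. By camera, ERK targets (adjusted p = 0.00027), glycolysis (0.0002), hypoxia (0.0027), immediate early genes (0.0045), NF-kB targets (0.013), oocyte markers (0.020) and smooth muscle markers (0.023) had higher values at 12 h and endothelial markers (0.0050) lower. The 12 h oocyte values again rested on siNTS library A_1. Of these lists 0 passed with an estimated correlation (adjusted p of 0.11 or more), and by fry 0 lists moved on balance (0.95). The oocyte list did not pass with the label block (0.083), and the surface epithelium list did (0.022; without the block, adjusted p = 0.76 with an estimated correlation).

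Whether the siRNA moved genes against hCG was asked across the genes, which are not independent replicates. Of the 2936 genes that passed with hCG at 4 h, 55.0% had a siRNA fold change of the opposite sign, as did 55.0% of the 2548 genes at 12 h. Both comparisons use the same siNC libraries with hCG. Unchanged groups, all simulated from a shared mean per gene and compared in the same way, gave 66.6% and 66.4%. They hold no hCG effect, so these shares are no chance level for genes selected by their hCG effect. With the hCG effect kept and no siRNA effect, the simulated shares were 50.1% (47.4% to 52.6%) and 50.2% (47.4% to 52.7%). The observed shares lay above these ranges and below the means of the unchanged groups. Simulated genes were drawn independently, so the ranges leave out any correlation between genes. The simulated libraries also held no pairing by label, which the real libraries did. With those siNC libraries split so that the comparisons shared none, the share averaged 52.1% at 4 h (29.5% to 73.1% over splits) and 54.0% at 12 h (44.8% to 64.6%). Over all tested genes, the covariance of the differences in mean log2 CPM was −0.0167 at 4 h and −0.0128 at 12 h, against −0.0486 and −0.0459 in the unchanged simulated groups, which puts it 0.0319 and 0.0331 above them. With a spread estimated after the label block, the simulated covariances were −0.0316 and −0.0303. When the comparisons shared no siNC libraries, the observed covariance over all genes averaged 0.0218 at 4 h (−0.0155 to 0.0688 over splits). At 12 h that average was 0.0255 (−0.0164 to 0.0595). Each split left the labels unbalanced, so both differences carried the same offset between labels. Same-label libraries deviated together, so this offset alone can raise the covariance and shift the share. The split values therefore do not decide whether the siRNA moved genes against hCG. Over only the genes called with hCG, the covariance lay below the simulated mean instead, at −0.0400 against −0.0367 at 4 h and −0.0398 against −0.0346 at 12 h. The simulated means for these genes were −0.0215 and −0.0227 with the block spread and with the hCG effect kept −0.0375 and −0.0358. The observed values lay inside the simulated ranges of the called genes without the block spread (−0.0436 to −0.0279 and −0.0407 to −0.0274) and below those with it (lowest −0.0289 and −0.0271). With the hCG effect kept, the ranges were −0.0646 to −0.0150 and −0.0633 to −0.0148, which hold the observed values.

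Time in culture was compared between control cells at 12 h and 4 h. The estrogen sulfotransferase gene Sult1e1 (Entrez 20860) fell from 71.0 ± 45.1 to 0.464 ± 0.438 CPM (−7.25 ± 0.60). Esm1 (−4.98), the decarboxylase gene Ddc (−4.34) and Pgr (−3.99 ± 0.65) fell next to Nts (−4.17 ± 1.29, adjusted p = 0.017). The call on Nts was lost without A_1 (adjusted p = 0.079), A_2 (adjusted p = 0.067), B_2 (adjusted p = 0.060) or the control library A_1 at 12 h (adjusted p = 0.055). Dpp6 (Entrez 13483) rose from 0.729 ± 0.205 to 29.3 ± 10.1 CPM (5.33 ± 0.37), followed by Naaladl2 (3.53), Ctnna2 (3.45), Smpx (3.18) and Ctrb1 (3.11). The inhibin gene Inha fell from 2222 ± 514 to 892 ± 135 CPM (−1.32), and the steroid dehydrogenase gene Hsd3b1 rose from 1938 ± 420 to 5059 ± 754 CPM (1.38). In all 2282 genes rose and 2468 fell, and 3137 passed without label A_2.

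Of 30 cell cycle genes 23 fell with time and 0 rose (25 and 0 adjusted over the list alone; camera adjusted p = 6.7e-11, and adjusted p = 0.0047 with an estimated correlation). Cdc20 (−1.10) and Aurkb (−1.03) were among them. Of 30 ovulatory genes 17 fell and 1 rose (18 and 1 adjusted over the list alone; camera adjusted p = 4.4e-10, and adjusted p = 0.34 with an estimated correlation). Cd44 (−2.21) and Btc (−3.43) fell. The unfolded protein response (12 of 21 fell, 1 rose; 14 and 1 adjusted over the list alone; camera adjusted p = 4.1e-06, and adjusted p = 0.22 with an estimated correlation) included the amino acid synthesis genes Asns (−2.69) and Psat1 (−2.71). Cholesterol synthesis was lower (13 of 23 fell, 1 rose; 14 and 1 adjusted over the list alone; camera adjusted p = 0.00099, and adjusted p = 0.58 with an estimated correlation). The p53 targets (10 of 22 fell; 0.0023, and adjusted p = 0.58 with an estimated correlation), immediate early genes (9 of 26 fell; 0.010, and adjusted p = 0.80 with an estimated correlation) and heat shock genes (8 of 21 fell, 1 rose; 0.015, and adjusted p = 0.46 with an estimated correlation) were lower too. Collagen and matrix genes were higher (11 of 23 rose, 1 fell; 0.0019, and adjusted p = 0.59 with an estimated correlation), with Col6a1 at 1.67. Clock genes were higher (8 of 19 rose, 1 fell; 0.0028, and adjusted p = 0.46 with an estimated correlation), with Dbp at 1.90 and Per3 at 2.28. Adjusted over the list alone, 2 clock genes and 10 immune markers fell, and the counts of the other lists from p53 targets on did not differ. Along with these groups, immune markers fell in 8 of 13 cases and rose in 0 (camera adjusted p = 0.00054, and adjusted p = 0.46 with an estimated correlation), with C1qb at −2.40. Surface epithelium markers fell in 6 of 7 and rose in 1 (0.0019, and adjusted p = 0.46 with an estimated correlation), with Krt18 at −1.79. The erythrocyte list passed only with the label block (0.20 without and 0.0046 with it; without it, adjusted p = 0.85 with an estimated correlation), and the other lists did not pass.

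In the authors' deposited tables, which hold their own fold changes and adjusted p-values, 1670 genes were higher and 2291 lower with hCG at 4 h, and 1799 and 1722 at 12 h. For Nts siRNA the authors' deposited tables list 17 genes higher and 43 lower at 4 h, and 122 and 209 at 12 h. Of the calls in the authors' deposited tables, 2831, 2449, 1 and 25 were shared in the same direction with the fit without a block. With the label block, 3944, 3500, 3 and 90 calls of the authors' deposited tables were shared. In the fit without a block, 0 were called in the opposite direction. In the authors' deposited table Nts has a log2 fold change of 2.94 with hCG at 4 h and 3.53 at 12 h. With its siRNA, the authors' deposited table lists −2.55 (adjusted p = 0.00034) at 4 h and −3.10 (adjusted p = 4.0e-05) at 12 h. A Benjamini-Hochberg adjustment of the p-values within each of the authors' deposited tables gave 4276, 3678, 3 and 79 genes.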

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

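For the control library A_1 at 12 h, the test of exchanged labels was chosen after the result was seen, and the 4 nuclear RNAs named for it were picked after their values were seen, as was Epcam for B_3; the test for B_3 on genes selected at 12 h was also chosen after the result was seen; the other tests in this part were set down before their results.

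In groups of 4, a library was singled out when its gap to the nearest other, divided by the group's range, exceeded Dixon's 95% limit; chance does this in about 1 in 20 groups, and here it held in 15 of 104. For Nts the B_3 library stood apart in siNC with hCG at 4 h (ratio 0.923, 180 against 28.7 CPM in the next library), siNTS with hCG at 4 h (0.941, 42.9 against 4.39 CPM), siNC with hCG at 12 h (0.853, 9.67 against 2.69 CPM) and siNTS with hCG at 12 h (0.971, 2.73 against 0.154 CPM). The total of estimated counts of B_3 in siNTS with hCG at 4 h also stood apart (0.881, 35.5 M against 44.2 M). In control cells at 4 h, B_3 stood apart for Ly6m (1), Pthlh (0.862), Ereg (0.82904), Star (0.962, 58.2 against 15.1 CPM) and Atoh8 (0.845), and A_1 for Ramp3 (0.856) and Slc24a4 (0.849). At 12 h B_3 stood apart for Edn2 in control cells (0.903) and for Vcam1 in control cells (0.993, 77.1 against 3.96 CPM) and with hCG (0.939).

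The hCG effect differed between 12 h and 4 h for 586 genes in a test of the difference itself. The largest differences were those of Hp (3.71), Ramp1 (3.66), Apln (3.44), Ptgfr (3.37) and Cdh15 (3.33), and of Pnoc (−3.58), Nmu (−3.23), Arl4d (−3.15), Adgrv1 (−3.10) and Npr3 (−2.99). Without label A_2 the calls on Hp (adjusted p = 0.052), Nmu (adjusted p = 0.16) and Npr3 (adjusted p = 0.066) were lost, and that on Nmu also without B_2 (adjusted p = 0.23) or B_3 (adjusted p = 0.15). Only 69 genes passed without A_2, 161 without B_2 and 314 without A_1.

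Nts was higher in B_3 than in the mean of the other labels in all 6 groups, by a mean log2 difference of 2.84, rank 3 among 11175 genes. A stronger response to hCG in that culture would raise the other induced genes as well, but over 1201 genes that rose with hCG at 4 h without B_3 the response in B_3 differed from the others by a median of −0.198, and was larger for 22.9% of them. Selecting genes by their response in the other labels lowers that median, so 1019 genes that rose at 12 h without B_3 were also compared at 4 h. For these the fold change in B_3 differed by a median of −0.0915, and the level with hCG by 0.0148 (quartiles −0.212 and 0.356), which argues against a stronger overall response as the whole cause. More cells of another type stay open: the highest of the lowest medians of a marker list was 0.310, for surface epithelium, which was higher in B_3 in all 6 groups (to 0.591), and Epcam was higher by 1.80. A list median would miss a small share of cells rich in Nts. A culture-date difference in the cells or in their handling stays open too and may be the source; no further biological explanation was tested.

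The control library A_1 at 12 h did not deviate from its group in the way of the other A_1 libraries: its correlation with their mean deviation was −0.660 across genes, while 21 of 24 libraries correlated best with their own label. It held 567 CPM of Xist against 57.0 to 141 in the other A_1 libraries, 253 of Neat1 against 13.1 to 21.01, 126 of Meg3 against 5.91 to 30.2 and 94.2 of Firre against 3.32 to 6.34. Over all other 23 libraries the highest values were nearer, at 287 CPM for Xist, 83.3 for Neat1, 82.6 for Meg3 and 25.5 for Firre. The control library A_1 at 12 h correlated best with the A_2 libraries (0.706), and B_2 of its group correlated more with the A_1 libraries (0.861) than with its own label (0.394). Yet exchanging these labels left the lower of the correlations, that of A_1 with the B_2 libraries, at −0.342. Removing a smooth trend on transcript length and GC content left −0.536, and the library's 36.0 M mapped reads lay within the 26.2 M to 45.4 M of the other 23 libraries. These argue against the exchange of A_1 and B_2, the length and GC trend and the number of reads, each as the whole cause. Exchanges among more labels of the group were not tested. The control library A_2 at 12 h correlated with the B_2 libraries at 0.155 and with its own label at 0.437. Deviations were centred within each group, so those of its libraries are not independent of each other. Wrong labels, of 1 library or of more, or a higher share of nuclear RNA in the control library A_1 at 12 h, may explain its deviation and remain untested.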

How the results depend on the processing

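Leaving out the control library A_1 at 12 h and restricting tests to genes without seed sites were tests chosen after the result was seen. Of 354 values of named genes, 345 passed, and 228 of these kept their direction and passed in every alternative; of 4587 alternative values 365 no longer passed, and 0 calls turned. The value of Cyp19a1, hCG at 4 h, which had not passed, ran from −0.0144 without B_3 to 0.32 without A_1. The counts moved as follows; the cause was not tested, except that fewer libraries carry less information. With the replicate block, hCG at 4 h gave 4642 genes, hCG at 12 h 4164 (4111 without control library A_1), Nts siRNA 3 at 4 h and 91 at 12 h, and the hCG difference between times 2174 (2202 without that library), and the lists called for Nts siRNA at 4 h became 5; Nts in siNTS cells at 12 h reached −2.76. Apart from these and the values given beside results, the block changed no other call named in the text. With culture date as the block, Nts siRNA gave 4 genes at 4 h and 75 at 12 h, the hCG difference 1748, and Nts itself −2.47 at 4 h and −2.79 at 12 h. DESeq2 gave 6, 61, 1061 and, for the difference of siRNA effects, 1. With no filter Nts siRNA at 12 h gave 14 genes and the hCG difference 385, with at least 1 CPM the former gave 38, and only the groups compared gave 1 there and 1770 for hCG at 4 h. Leaving out 1 label gave 1283 to 2485 genes for hCG at 4 h, 1268 to 2299 at 12 h, 0 to 3 and 0 to 40 for Nts siRNA at 4 h and 12 h, 69 to 432 for the hCG difference (466 without only the control library A_1 at 12 h), and 3137 to 4475 for time. Among genes without seed sites, Nts siRNA gave 0 genes at 4 h and 0 at 12 h, and with the block 0 and 6. With an estimated correlation the lists called went to 1 and 3 for hCG at 4 h and 12 h, 0 for both siRNA contrasts and both differences, and 1 for time; fry, which asks whether a list moved one way, called 0 lists for the siRNA contrasts and their difference and 3 for the hCG difference. Splitting the siNC libraries with hCG gave 52.1% opposite signs at 4 h. The simulated recovery of 19.4% of 1.5-fold changes at 4 h, which left out genes of low level, shows what the fit without a block could miss. The spread of that fit includes differences between labels, so the recovery says nothing on the fit with the label block.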

Other observations

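The 7-base sequences and the gene groups without seed sites, the genes named for B_3, the oocyte sums and the splits that exchange whole pairs were tests or values chosen after the result was seen.

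Besides Nts, the B_3 libraries held more of several inflammatory genes than the other labels did. Averaged over the 6 groups, the chemokine gene Cxcl1 was higher in B_3 by a log2 of 5.73, the collagenase gene Mmp13 by 3.51, the NF-kB regulators Nfkbiz by 2.74 and Tnfaip3 by 1.83, Vcam1 by 2.04, Serpinb2 by 1.86 and the RNase gene Zc3h12a by 1.74. Genes of other kinds differed less than Cxcl1, Mmp13 and Nfkbiz but about as much as the rest of these. They were Dmbt1 (2.07), the neuropeptide gene Npy (1.87), Egln3 (1.82) and the epithelial marker Epcam (1.80). Of 19 genes in the list of cytokines and NF-kB targets, 18 were higher in B_3, with a median difference of 0.842 and group medians from 0.362 to 1.78. For Vcam1 the difference lay mostly at 12 h, with 77.1, 3.97 and 21.1 CPM in B_3 of control, siNC with hCG and siNTS with hCG against 3.96, 1.07 and 1.09 CPM in the next library, and at 4 h with 5.49, 2.96 and 2.53 against 4.51, 2.49 and 2.14 CPM. With 1 culture under that label in each group, this difference has no replicate of its own.

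The summed level of 14 oocyte markers was mostly higher at 4 h than at 12 h and varied widely within groups. The sum reached 42.5 CPM in control cells at 4 h (B_2), 31.6 in siNTS with hCG at 4 h (B_2), 25.8 in siNC with hCG at 4 h (A_1), 21.6 in siNTS with hCG at 12 h (A_1) and 20.05 in control cells at 12 h (B_3), while the lowest was 8.39 CPM among the 4 h libraries and 4.14 CPM among the 12 h libraries. The ribosomal protein gene Rps27 stood at 1.62, 0.977 and 0.704 CPM in siNC with hCG at 4 h (B_3), siNC with hCG at 12 h (A_2) and siNTS with hCG at 12 h (A_2), where its near-identical copy Rps27rt stood at 274, 328 and 243 CPM. Their sum ran from 244 to 1159 CPM over libraries, so neither is reported as a result.

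The genes lower with Nts siRNA at 12 h may be direct targets of the siRNA's seed, the bases by which a small RNA pairs with 3′ UTRs; this is a hypothesis found in the same genes, since the siRNA sequence was not known. Of 16362 sequences of 7 bases, TGACAAA had the lowest z over 1414 genes that carry it (−20.6, mean shift −0.094), below the lowest of the 7 other ways to part the label pairs (−13.8). That value is no chance level: with only A_1, A_2, B_2 or B_3 exchanged, part of the real effect remains. TGACAAA was again lowest in those splits (−13.8 to −12.3). With A_1 and another label exchanged, the lowest z of any sequence was −5.41 to −4.80. These 8 splits are too few for a share under 0.05. TGACAAA lies once in the Nts transcript, at positions 273 to 279 in exon 2, GRCm38 chromosome 10 from 102487947 to 102487953, where 7.17% of all such sequences would occur by chance. The highest z, 11.8 for GACGTAA against 8.36 in the other splits, is likewise consistent with genes freed from a control siRNA's seed, and 4 of the 6 genes that rose and have a 3′ UTR carry that site, against 1.47% of genes. Loss of Nts stays open for 2 genes with neither 6-base core, Ugcg and Rbm18, and for 5 lower and 9 higher genes with neither core among the calls with the label block, and for the others seed pairing and loss of Nts cannot be told apart without a second siRNA. The forecast had named blocked fold changes while the scan used mean differences of log2 CPM within labels, and an earlier exploratory scan had been seen.

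The shift was graded by the length of the match: the median siRNA effect at 12 h was −0.114 for 447 genes with an 8-base match (78.1% lower), −0.050 for 967 with 7 bases, −0.012 for 2001 with the 6-base core and 0.034 for 6800 with neither core. At 4 h the same sequence had the lowest z (−17.5, others to −10.4, again TGACAAA, with B_3 exchanged). But the highest z, 8.97 for GACGTAA, did not exceed the other splits (9.53 for TGTAAAT with A_1 exchanged). With hCG the lowest z of any sequence in the real split was −4.79 at 4 h and −4.71 at 12 h. With A_1 and A_2 exchanged, TGTAAAT reached −9.85 at 4 h and 10.1 at 12 h in the hCG comparisons. Differences between labels can thus give z values of that size without a seed. With the label block, 54 of 59 genes that fell at 12 h and have a 3′ UTR carried the core and 43 the site, while of 26 genes that rose and have a 3′ UTR 16 carried the control core and 9 the control site, against 4.84% and 1.47% of genes. Ell2, chosen after its values were seen, carries the site and stood at −0.93 (adjusted p = 0.32) and at −0.95 with the block (adjusted p = 0.00073).

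Other splits of the same libraries were run to see whether chance could give as many genes. For hCG at 4 h the real split gave 2936 genes and 1 of 35 splits, the real one, gave as many, with 989 in the highest other. For hCG at 12 h the values were 2548 and 0 (1 of 35), for Nts siRNA 1 and 0 at 4 h and 25 and 0 at 12 h (each 1 of 35), and for time 4750 and 0 (1 of 35). The real split was thus alone in giving as many genes, but these splits ignore the label pairs. Same-label libraries deviated together (17 of 20 pairs over 0.1), so splits that keep pairs together are not equal alternatives to the real one. The 35 splits therefore do not decide whether chance gave these counts. The counts for Nts siRNA fell to 0 without A_2, B_2 or B_3, with the changes kept in size. Capn10 stood at −1.48, −1.40 and −1.27 at 12 h (−1.35 with all labels) and at −1.19, −1.10 and −1.16 at 4 h (−1.13). For the hCG difference between times, 6 of 100 splits gave as many as 586, with 4258 in the highest other. For the siRNA difference the real count was 0, which 100 of 100 splits reach by definition (highest other 6239). Those splits mix times and treatments, and their large counts point to that structure, so they decide nothing about chance for either difference. When whole pairs exchanged their time labels, the hCG difference gave 761 genes against 1 in the highest other of 35 splits. The real split alone gave as many genes. Both times carry the same labels, so these splits too may not be equal alternatives to it. With the label block and every pair parted there were 8 splits, too few for a share under 0.05, and the real and highest other counts were 4642 and 0 for hCG at 4 h, 4164 and 0 at 12 h, 3 and 0 and 91 and 0 for Nts siRNA, and 6666 and 1777 for time.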
